A study of Mus musculus with 2 samples.

How the data were processed

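Poly(A) RNA of mouse E14 embryonic stem (ES) cells, a line of the 129P2/OlaHsd strain, was compared before and after differentiation. The undifferentiated cells grew on mitotically inactivated mouse embryonic fibroblasts in medium with 15% serum and leukaemia inhibitory factor, which keeps mouse ES cells in self-renewal. The differentiated cells were plated without feeder cells in 10% serum with retinoic acid at 0.1 µM, and were harvested after 4.5 days as a mixed population. Per the labels' protocols, feeder cells were removed by letting them settle on culture plates, with less than 0.25% estimated to remain, and dead cells made up about 2% of the undifferentiated and 8% of the differentiated harvest. Both cultures were at passage 29. Libraries were made from 5 µg of total RNA with an Illumina mRNA kit, size-selected at about 250 bp and read as 36 bp single-end reads on 2 lanes each of a Genome Analyzer IIx, per the labels' protocols. The 2 samples form 2 groups of 1 library each.

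The authors deposited 3 tables, for genes (34376 rows), promoters (55830 groups of transcripts with a common first exon) and transcripts (83402 rows). Each gives the values of the 4 lanes and the mean of both lanes of a library. The unit is not named in the tables. The deposited values were read as RPKM, read numbers divided by the length of the model and the read total of the lane, because in single-exon genes the value times the length mostly fell on whole multiples of a constant. Of the low values of 7876 such genes (above 0, with value times length under 1000), 3546 to 3590 in each lane, 81.8% to 82.4% did so within a tolerance of 5% of a read. Column sums differed between libraries (989605 and 836419 RPKM), as they cannot in TPM. The value of 1 read implied about 37800000 and 36200000 reads in the undifferentiated lanes and 33100000 and 32000000 in the differentiated lanes, so that 1 RPKM in a 1 kb model stood for 32.0 to 37.8 reads of a lane. The deposited averages equalled the lane means, and the gene values equalled the sums over transcripts. Coordinates are those of the tables, on build mm9 per the submitters' processing notes, and are printed with the first base counted as 1. The aligner, the counting program, the gene annotation and the treatment of reads that match several places are not given in the sources used here. The kit named in the labels does not record the strand, so overlapping and antisense genes share reads. Near-identical gene copies share reads too, and their values are uncertain.

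Ratios were computed as log2 of (differentiated RPKM + 1) over (undifferentiated RPKM + 1), which understates differences of weakly expressed genes. Genes with at least 1 RPKM in either library were counted as higher or lower at a 2-fold difference on this scale. With 1 library per group, no test between the conditions exists and no p-value is given. The SD of the 2 lanes, and the standard error of a log2 ratio derived from it, cover sequencing and read assignment alone, since both lanes hold the same library. A test on counts was not run because the values are RPKM. The tables used here hold no fold changes or p-values of the authors. All columns of values were matched to a sample.

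The 27 gene lists (12 main and 15 others) were fixed before the data were examined. They covered the cell states and lineages that retinoic acid could give, feeder fibroblasts, imprinted genes, CTCF and cohesin, chromatin regulators, cell cycle, stress, metabolism and reference genes. Symbols were matched without regard to case, and through synonyms of the RefSeq gene table of assembly GRCm38.p6, used for names alone, where the symbol was missing. Synonyms placed 1 gene each in the pluripotency, neuron, mesoderm and trophectoderm lists and 2 in the neural crest list. Hoxd12, Mirg, Prl3d1, Psx1, Tcstv1, Tcstv3, Hba-x and Myod1 were not matched and are not analysed here. Of rows with the same symbol (488 rows), the row with the highest mean was used. For each list the median log2 ratio of members at the floor was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5, as a description of these libraries.

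Genes were named by a rule fixed before the data were examined. It took Pou5f1, Nanog, Zfp42, Cyp26a1, Rarb and Ctcf always, with a further gene that is not reported here, then the 3 members of each main list and the 2 members of each other list with the largest absolute log2 ratio. It added the 6 genes with the highest and the 6 with the lowest ratio among genes with an informative symbol and at least 10 RPKM in either library. Any gene named outside the rule is said to be chosen after its values were seen. For genes with at least 2 promoters, or transcripts, and a sum of at least 5 RPKM in both libraries, the share of each promoter or transcript in the gene's sum was compared at a difference of 30 percentage points. The 5 genes with the largest difference were named.

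Other settings, chosen before the data were examined, were pseudocounts of 0.1 and 0.5, no floor or a floor of 5 RPKM, centring on the median, trimmed-mean scaling (30% of ratios and 5% of levels trimmed from each end), upper-quartile scaling, sums over transcripts or promoters, thresholds of 4-fold and 1.5-fold, unmatched random lists, lists without genes held by several lists, and other limits for shares. Settings chosen after seeing the data were single lanes, genes whose lanes lay within 2-fold of each other, equal RPKM sums, genes with informative symbols, and shares that differ in all 4 pairings of lanes. The calculation was tested on simulated data for this comparison over 34376 genes. All 100 genes planted 4-fold higher and all 100 planted 4-fold lower were recovered, with 0 of the other genes called, and 8 of 200 unshifted lists fell outside the percentile limits. The planted genes had a mean of 10 RPKM or more, and the simulation held Poisson read error alone, with the same length for all models. It checks the calculation and cannot show the error between lanes or cultures. Calculations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, figures Matplotlib 3.10.9, and a search for Gapdh-like sequences blastn 2.17.0 on GENCODE M21 transcripts (at least 90% identity over more than 300 bp), from which names but no coordinates were taken.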

Results

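RNA sequencing of E14 mouse ES cells recorded gene expression in 1 undifferentiated library and in 1 library of the mixed population obtained after 4.5 days in 0.1 µM retinoic acid. The comparison asks which genes differ in expression before and after differentiation, in a study whose title concerns binding sites of the insulator protein CTCF. Values are RPKM read from the authors' deposited tables, and an error after ± is the SD of the 2 lanes of a library. The lanes implied about 37800000 and 36200000 reads for the undifferentiated library and 33100000 and 32000000 for the differentiated library. Lanes differed little: among genes at 10 RPKM or more, 98.6% of 7875 in the undifferentiated and 98.4% of 8877 in the differentiated library lay within 2-fold between lanes, and the median difference was 1.05-fold in both. There are no replicate cultures, so no difference below has a replicate check, and the lane SD covers sequencing and read assignment alone.

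Most pluripotency genes were lower in the differentiated library, and most genes of the extraembryonic endoderm, retinoic acid pathway and imprinted lists were higher. Col4a2 and Col4a1, the adjacent genes of type IV collagen, the main collagen of basement membranes, were among the 6 genes with the highest ratios. Col4a2 stood at 5.43 ± 0.253 RPKM in the undifferentiated and 957 ± 12.3 in the differentiated library (log2 ratio 7.22), and Col4a1 at 12.5 ± 0.272 and 1755 ± 32.1 (7.03). The others were Cyp26a1, Igf2, Pth1r, the receptor for parathyroid hormone and its related peptide (0.643 ± 0.0771 and 160 ± 6.97, 6.61), and Serpinh1, the collagen chaperone Hsp47 (10.7 ± 0.478 and 1003 ± 3.10, 6.42). At the other end stood Nr0b1, Esrrb and Trh, which encodes the precursor of thyrotropin-releasing hormone (230 ± 2.36 and 2.20 ± 0.658, -6.17). Of 18019 genes at the floor of 1 RPKM, 3446 were at least 2-fold higher in the differentiated library, 1524 were at least 2-fold lower and 13049 lay between.

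Of the genes past 2-fold, 69.3% were higher in the differentiated library. That split depended on the scaling: it was 59.4% after centring on the median, 58.2% after trimmed-mean and 61.1% after upper-quartile scaling, and 80.6% with equal RPKM sums, and it was 76.0% among the 12190 genes with informative symbols. The median log2 ratio of all genes at the floor was 0.124 in the values as deposited, and over the same 18019 genes these scalings shifted it by -0.124, -0.143, -0.108 and 0.206, so ratios of that size carry no direction. For 3 of the 6 lowest genes the ratio rested on 1 lane. In the undifferentiated library Obox3 stood at 217 ± 305.6 RPKM, Cnnm1 at 68.6 ± 95.8 and Dleu2 at 39.2 ± 55.3, and their log2 ratios in the separate lanes were -0.73 and -7.82, -0.42 and -6.83, and -6.31 and -0.18.

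**Figure D1:**
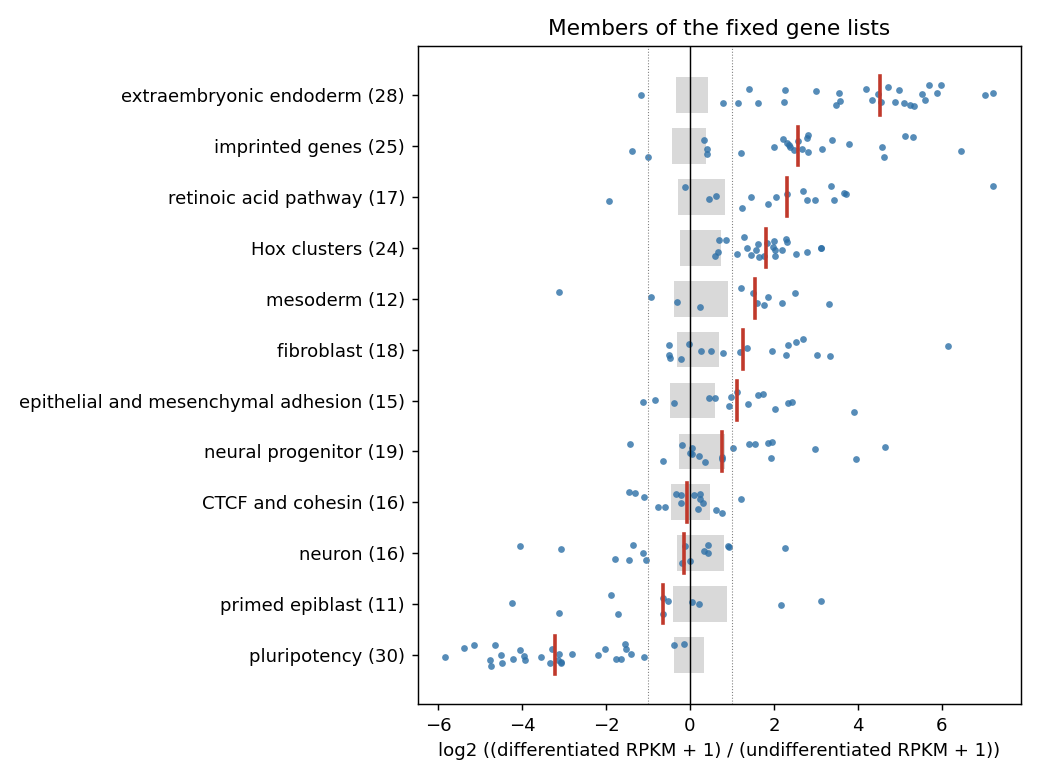
Each point is a member gene of a main list with at least 1 RPKM in either library, placed by its log2 ratio of differentiated over undifferentiated RPKM (pseudocount 1), with the number of genes in parentheses, the list median as a red bar and the central range of the medians of 10000 matched random lists that leaves out 2.5% at each end as a grey box. Medians ran from -3.22 for pluripotency genes to 4.52 for extraembryonic endoderm genes, and those of the neuron list (-0.15) and the CTCF and cohesin list (-0.06) turned positive with equal RPKM sums.

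Pluripotency genes were lower almost throughout. Of 30 members at the floor, 28 were at least 2-fold lower in the differentiated library, none was 2-fold higher, and Socs3 and Lin28a, named after their values were seen, lay between (log2 ratios -0.13 and -0.39). Pou5f1, which encodes the POU factor Oct4 (mm9 chromosome 17, 35642984 to 35647722), stood at 692.5 ± 9.0 RPKM in the undifferentiated and 29.5 ± 0.295 in the differentiated library, a log2 ratio of -4.51. Nanog, a homeobox factor of the ES cell network (chromosome 6, 122657507 to 122664651), stood at 140 ± 1.82 and 2.96 ± 2.00 RPKM (-5.15), with -4.72 and -5.78 in the separate lanes. Zfp42, the zinc finger gene also called Rex1 (chromosome 8, 44380421 to 44392363), stood at 283.5 ± 3.76 and 9.70 ± 0.108 (-4.73). Esrrb, an orphan nuclear receptor of naive cells, was at 163 ± 1.74 and 2.93 ± 0.0265 (-5.38), and Nr0b1, the nuclear receptor Dax1, at 121 ± 1.26 and 1.15 ± 0.0941 (-5.83). The list median of -3.22 lay at percentile 0 of matched random lists.

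Genes of the primed epiblast, the state after implantation, went both ways. Of 11 members 4 were lower, 2 were higher and 5 lay between, and the median of -0.64 lay at percentile 0.41. Foxd3, a forkhead repressor, stood at 24.0 ± 0.319 and 0.330 ± 0.0166 RPKM (log2 ratio -4.23), and Otx2, a homeobox factor of the epiblast and forebrain, at 24.3 ± 0.418 and 1.90 ± 0.984 (-3.13). Cldn6, a tight junction claudin that epithelia other than the epiblast also express, was higher, at 13.4 ± 0.0754 and 124 ± 2.53 (3.12).

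The genes that bind, make and break down retinoic acid were higher as a group. Of 17 members at the floor 13 were higher, 1 was lower and 3 lay between, with a median log2 ratio of 2.31 at percentile 100. Cyp26a1, the cytochrome P450 that breaks down retinoic acid (chromosome 19, 37772298 to 37776026), was at 0.70 ± 0.12 RPKM in the undifferentiated and 253 ± 16.2 in the differentiated library (7.22). Its relative Cyp26b1 stood at 0.40 ± 0.303 and 17.3 ± 0.16 (3.71). Rarb, a retinoic acid receptor gene that is itself a direct target of the receptors (chromosome 14, 17263354 to 17651381), stood at 0.226 ± 0.0867 and 14.5 ± 1.31 (3.66). The 1 lower member was Rarg, named after its values were seen, another receptor gene, at 49.2 and 12.2 RPKM (-1.92).

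The Hox genes, which pattern the body axis, were nearly silent before differentiation and present at low levels after it. Of 38 genes measured, 24 reached the floor, of which 20 were higher, none was lower and 4 lay between (median log2 ratio 1.80, percentile 100). No Hox gene reached 1 RPKM in the undifferentiated library, so the floor admitted genes by their level after differentiation alone. Over all 38 genes the median was 1.20, at percentile 100. Higher members made up 11 of 12 at the floor in paralogue groups 1 to 5, 9 of 9 in groups 6 to 9, and 0 of 3 in groups 10 to 13. With a pseudocount of 0.1 all 24 genes at the floor were higher, so the difference between groups in these counts depends on the pseudocount. The highest level in the differentiated library was 10.2 RPKM. Hoxa3 stood at 0.0795 ± 0.00195 and 8.43 ± 0.489 (3.13), Hoxa5 at 0.0294 ± 0.00528 and 7.93 ± 0.616 (3.12), and Hoxb9 at 0.625 ± 0.00972 and 10.2 ± 0.24 (2.78). The annotated models of Hoxa3 (52119061 to 52163335) and Hoxa5 (52151753 to 52154586) overlap on chromosome 6.

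Markers of extraembryonic endoderm, the epithelium that lines the yolk sac, had the highest median of the main lists. Of 28 members 26 were higher, 1 was lower and 1 lay between, with a median log2 ratio of 4.52 at percentile 100. Besides Col4a1 (chromosome 8, 11198423 to 11312826) and Col4a2 (11312805 to 11449287), whose models overlap at their ends, the rule named Cubn, the endocytic receptor cubilin of the visceral yolk sac, at 1.08 ± 0.16 and 129 ± 0.356 RPKM (5.97). The transcription factors Gata4, Gata6, Sox17 and Foxa2, named after their values were seen, had ratios of 5.89, 4.72, 4.99 and 4.34. The member below was Apoe (-1.16), an apolipoprotein gene that was already at 212 RPKM in undifferentiated cells. Keratin genes, which the trophectoderm also expresses, are among the members.

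Neural genes were mixed. Of 19 neural progenitor genes at the floor 9 were higher, 1 was lower and 9 lay between, and the median of 0.77 at percentile 95.95 did not stand apart, although it did in 10 of 16 alternative settings. With no floor it was 0.24 at percentile 86.61 over all 28 members. Meis1 and Meis2, TALE homeobox partners of Hox proteins that are also expressed outside the nervous system, stood at 0.379 ± 0.00573 and 33.6 ± 1.55 RPKM (log2 ratio 4.65) and at 2.01 ± 0.69 and 45.7 ± 2.52 (3.96). Nes, which encodes the intermediate filament nestin, was at 3.15 ± 0.0183 and 31.7 ± 0.27 (2.98). Of 16 neuron genes at the floor, 7 were lower, 1 was higher and 8 lay between (median -0.15, percentile 7.90). The median was positive with equal RPKM sums and with no floor (0.05, percentile 38.37, 25 genes), but stood apart on the lower side in lane 2 (-0.65, percentile 0.10) and among genes with lanes within 2-fold (-0.61, percentile 0.05). Stmn2, a stathmin of growing axons, stood at 248 ± 4.74 and 14.02 ± 1.81 (-4.05), and Ina, the neurofilament alpha-internexin, at 20.7 ± 2.05 and 1.59 ± 0.0604 (-3.07). Gap43, a growth cone protein gene, was higher, at 2.69 ± 0.185 and 16.7 ± 0.659 (2.26). The neural crest list held 5 higher and 1 lower of 9 genes (median 1.08, percentile 97.91). It no longer stood apart in 4 settings, at percentiles of 92.44 with no floor, 93.25 in lane 1, 93.43 with lanes within 2-fold and 93.97 with informative symbols. The list was led by Sox9, which cartilage and endoderm also express, at 0.668 ± 0.0717 and 17.8 ± 2.21 (3.49), and Ets1, which endothelium also expresses, at 0.784 ± 0.139 and 16.5 ± 0.0628 (3.30).

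Mesoderm genes were higher at the floor, though many stayed silent in both libraries. Of 12 members at the floor 8 were higher, 1 was lower and 3 lay between (median 1.56, percentile 100). With the 7 members below the floor included, the median was 0.25 and no longer stood apart (percentile 92.24). The primitive streak genes T, Mesp1 and Mixl1 and the heart gene Tbx5, named after their values were seen, are among those 7. Hand2, a helix-loop-helix factor of heart and limb, stood at 0.0183 ± 0.000569 and 9.20 ± 1.24 RPKM (3.32), and Twist1, a related factor of mesenchyme, at 1.82 ± 0.0565 and 14.9 ± 1.59 (2.5). Tcf15, a paraxial mesoderm factor that ES cells primed to differentiate also express, was lower, at 54.5 ± 1.46 and 5.45 ± 0.385 (-3.11). Of 8 muscle genes 4 were higher and none was lower (median 1.12, percentile 98.31). The list did not stand apart at a floor of 5 RPKM (percentile 81.88), in lane 1 (96.28) or with informative symbols (95.75). It includes Actc1, cardiac actin, at 0.823 ± 0.201 and 43.2 ± 3.0 (4.60), whose sequence is close to that of other actins, and Myh7, a cardiac myosin heavy chain, at 1.46 ± 0.343 and 6.97 ± 0.693 (1.70). The endothelium and blood list did not stand apart (3 higher and 1 lower of 7, median 0.42, percentile 46.05), and with no floor its median was below 0 (-0.06, percentile 9.62, 13 genes). In it Flt1, a VEGF receptor gene that parietal endoderm and trophoblast can also express, stood at 0.828 ± 0.189 and 32.8 ± 0.77 (4.21), and Pecam1, an adhesion receptor that ES cells express too, at 15.9 ± 3.71 and 1.26 ± 0.182 (-2.90).

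Adhesion genes of epithelium and mesenchyme were higher as a list, with members of both kinds on either side of 2-fold. Of 15 adhesion genes 8 were higher, 1 was lower and 6 lay between (median 1.13, percentile 99.94). Cdh2, N-cadherin, was at 2.06 ± 0.0471 and 44.7 ± 3.19 RPKM (3.90), and the repressors Zeb2 and Snai1 at 0.511 ± 0.142 and 7.18 ± 0.472 (2.44) and at 4.63 ± 0.198 and 27.2 ± 1.35 (2.33). Among epithelial members, named after their values were seen, Cdh1, E-cadherin, was at 103 and 78.5 RPKM (-0.39), Epcam was the lower gene (-1.11), and the claudin gene Cldn7 was higher (1.74). Of 18 fibroblast genes at the floor 10 were higher, none was lower and 8 lay between (median 1.27, percentile 100). Tagln, an actin-binding protein of smooth muscle, stood at 8.33 ± 0.848 and 660 ± 2.41 (6.15), and the fibrillar collagen genes Col1a1 and Col3a1 at 12.3 ± 1.41 and 133 ± 0.791 (3.33) and at 3.61 ± 0.0866 and 36.4 ± 2.56 (3.02). The labels put leftover feeder fibroblasts below 0.25% of cells. Of 6 trophectoderm genes at the floor 4 were higher and 1 was lower (median 2.17, percentile 99.96). With the 3 members below the floor included the median was 0.28 and no longer stood apart (percentile 77.98). Those 3, named after their values were seen, were Cdx2 (0.449 and 0.651 RPKM), Elf5 (0.198 and 0.444) and Tpbpa. The lower member, named likewise, was Tfap2c (24.45 and 6.36 RPKM, -1.79). Plac1, a placental gene, was at 0.0149 ± 0.0211 and 6.68 ± 0.683 (2.92). The value of the keratin gene Krt7, 4.09 ± 1.56 and 145 ± 152 (4.84), differed between lanes, with log2 ratios of 5.99 and 2.62.

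Imprinted genes, expressed from the allele of a single parent, were higher across several clusters. Of 25 members at the floor 20 were higher, 1 was lower and 4 lay between, with a median log2 ratio of 2.58 at percentile 100. Igf2, which encodes the fetal growth factor insulin-like growth factor II (chromosome 7, 149836673 to 149847210), stood at 3.79 ± 0.911 RPKM in the undifferentiated and 416.5 ± 3.55 in the differentiated library (6.45). Its neighbour H19, a noncoding RNA gene controlled by the same CTCF-bound imprinting region (149761434 to 149764051), stood at 28.5 ± 0.938 and 1028 ± 17.8 (5.12). Peg3, a paternally expressed zinc finger gene (chromosome 7, 6656603 to 6683132), stood at 4.66 ± 0.291 and 223 ± 1.38 (5.31). The lower member was Snrpn, named after its values were seen (54.6 and 20.4 RPKM, -1.38). The values are totals of both alleles.

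**Figure D2:**
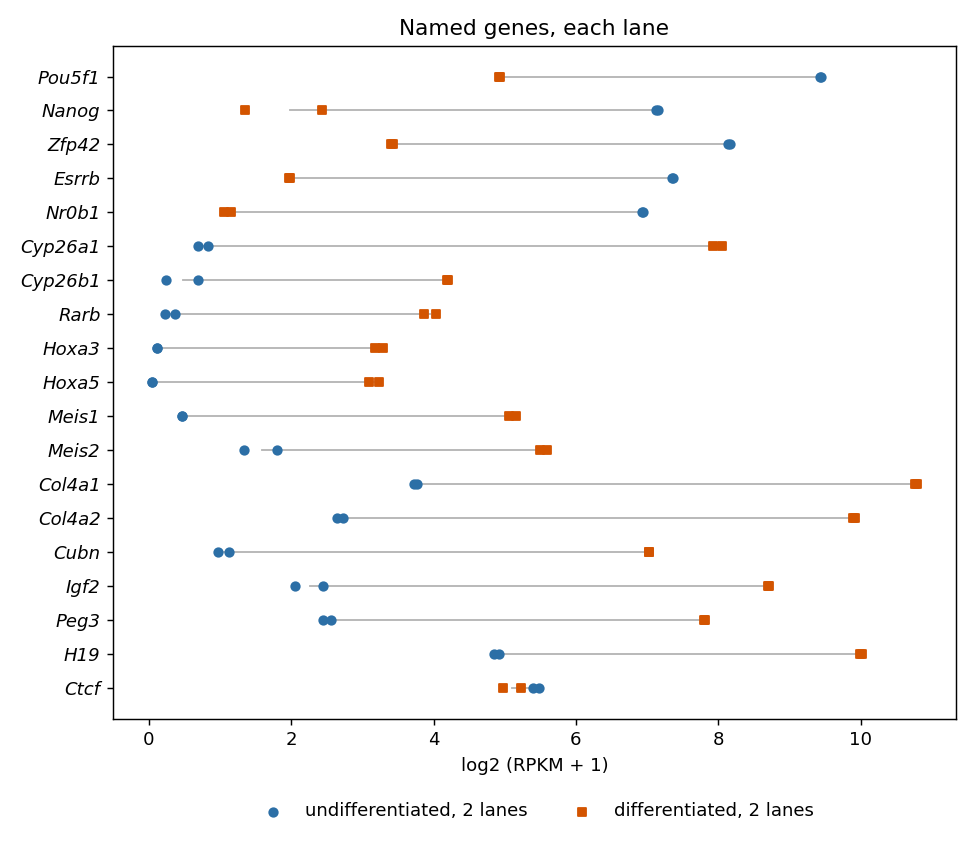
Expression of 19 named genes, with each point the log2 of RPKM + 1 of a single lane, blue circles for the undifferentiated and orange squares for the differentiated library, and a grey line joining the library means. Lanes of a library lie farthest apart for Nanog in the differentiated library, and Ctcf has the smallest distance between libraries of the 19 genes (42.3 and 33.4 RPKM).

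Ctcf itself differed by less than 2-fold, and the list of CTCF and cohesin, which meet at chromatin loop anchors, did not stand apart. Ctcf (chromosome 8, 108160438 to 108206822) stood at 42.3 ± 1.68 RPKM in the undifferentiated and 33.4 ± 4.23 in the differentiated library, a log2 ratio of -0.33 that ranged from -0.10 to -0.50 over the scalings. Of 16 members at the floor 12 lay between, 3 were lower and 1 was higher (median -0.06, percentile 39.97, positive with equal RPKM sums). The lower ones included Cdca5, sororin, which holds sister chromatids together (45.1 ± 0.57 and 15.8 ± 0.377, -1.46), and Esco2, the acetyltransferase that locks cohesin in S phase (43.6 ± 3.01 and 16.9 ± 3.22, -1.32). Stag2, a cohesin subunit, was higher (12.8 ± 0.512 and 30.8 ± 0.835, 1.21).

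Within the DNA methylation and Polycomb machineries single genes went opposite ways and neither list stood apart. Tet1, a 5-methylcytosine oxidase of ES cells, stood at 18.8 ± 1.36 and 2.77 ± 0.525 RPKM (-2.39), and its relative Tet3 at 0.919 ± 0.36 and 16.8 ± 8.01 (3.21, with 2.48 and 3.82 in the separate lanes). Of 15 methylation genes 5 were lower and 2 were higher (median -0.06, percentile 43.23). Phc1, a subunit of Polycomb repressive complex 1, was at 179 ± 0.232 and 25.6 ± 1.98 (-2.76), and its paralogue Phc2 at 7.10 ± 0.901 and 42.0 ± 0.028 (2.41). Of 20 Polycomb genes 4 were higher and 4 were lower (median 0.07, percentile 58.68). The sign of both medians turned under at least 1 scaling.

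Proliferation genes were lower as a list, and G1 regulators were higher, mostly through inhibitor genes. Of 20 proliferation genes 7 were lower and none was higher (median -0.77, percentile 0.03). The replication helicase genes Mcm7 and Mcm5 stood at 181 ± 3.43 and 58.6 ± 1.42 RPKM (-1.61) and at 192 ± 3.64 and 72.5 ± 1.82 (-1.39). The other lower members, named after their values were seen, were Mcm2, Mcm3, Mcm6, Pcna and Ccne1. Ccnb1, Plk1 and Mki67, named likewise, lay between (-0.92, -0.46 and 0.23). Of 10 G1 regulators 5 were higher and none was lower (median 1.09, percentile 99.6), with Ccnd2, cyclin D2, at 1.66 ± 0.582 and 53.2 ± 2.30 (4.35) and the inhibitor Cdkn2b at 1.60 ± 0.435 and 21.2 ± 0.793 (3.09). The inhibitor genes Cdkn1a, Cdkn1b and Cdkn2a, named after their values were seen, were also higher (2.37, 1.26 and 2.70). The cyclin genes Ccnd1 and Ccnd3, named likewise, lay between (-0.35 and -0.47). Of 16 genes of the p53 and cell death list 6 were higher and none was lower (median 0.68, percentile 99.47, and 96.68 against unmatched lists), among them Gadd45g, a growth arrest gene (1.56 ± 0.00739 and 32.6 ± 2.86, 3.71), and Fas, a death receptor (0.549 ± 0.632 and 4.47 ± 1.06, 1.82, with 2.5 and 1.24 in the separate lanes). Immediate early and heat shock genes, which also respond to cell dissociation, were higher in 11 of 13 and lower in none (median 2.08, percentile 100). Jun stood at 7.44 ± 0.182 and 93.4 ± 0.819 (3.48) and Atf3 at 5.60 ± 1.75 and 69.0 ± 2.54 (3.41). Both harvests were dissociated with trypsin, and the labels estimate dead cells at 2% in the undifferentiated and 8% in the differentiated harvest.

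Germline genes were lower as a list, with members on both sides of 0. Of 10 germline genes 5 were lower and none was higher (median -1.11, percentile 0.01), with Sycp3, a component of the synaptonemal complex, at 26.3 ± 1.55 and 0.189 ± 0.267 RPKM (-4.52) and Tex19.1 at 88.0 ± 0.502 and 18.6 ± 0.403 (-2.18). Genes of the 2-cell-like state, which rare ES cells enter, lay between in 6 of 6 cases (median 0.61, percentile 86.14). All 6 are Zscan4 copies that share reads, among them Zscan4c (21.3 ± 1.22 and 35.5 ± 1.20, 0.71) and Zscan4f (13.3 ± 1.10 and 22.9 ± 1.22, 0.74). In the signalling feedback list 6 of 16 genes were higher and 5 lower (median 0.13, percentile 54.36, below 0 after trimmed-mean scaling). Etv5 and Spry4, which are targets of fibroblast growth factor signalling, stood at 173 ± 4.36 and 11.0 ± 1.59 (-3.86) and at 14.7 ± 0.0233 and 1.66 ± 0.0208 (-2.56). Dusp6, another member of the list, named after its values were seen, was higher (19.6 and 42.9 RPKM, 1.09).

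Glycolysis genes were lower as a list, with 5 of 20 lower and 1 higher (median -0.69, percentile 1.44). Pfkp, the platelet form of phosphofructokinase, stood at 111 ± 2.39 and 5.28 ± 0.271 RPKM (-4.16). Gapdh, the glyceraldehyde-3-phosphate dehydrogenase gene (chromosome 6, 125111870 to 125115791), was listed at 828.5 ± 16.9 and 70.8 ± 11.6 (-3.53), but an overlapping model inside its end, Gm10481, was listed at 0 in both undifferentiated lanes and at 266 RPKM in the differentiated library, and the sum of both had a log2 ratio of -1.30. Of 13 reference genes 10 lay between, 2 were lower and 1 was higher (median 0.07, percentile 96.5, below 0 after median centring, and apart in lane 1 at percentile 98.30). Hprt, of purine salvage, stood at 77.4 ± 2.48 and 35.5 ± 1.80 (-1.10) and Gusb, a lysosomal glucuronidase gene, at 6.78 ± 1.34 and 18.2 ± 0.578 (1.30).

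Some genes differed between the libraries in the share of their sum listed for a start or form. How reads that fit several forms were assigned is not given in the sources used here. An assignment that differed between libraries but not between lanes would pass all 4 pairings of lanes. Whether the start or form itself changed was therefore not tested. Of 4579 genes with at least 2 promoters and 5 RPKM in both libraries, 207 (4.52%) had a promoter whose share of the gene's sum differed by at least 30 percentage points, and 112 had this in all 4 pairings of lanes. Of 6170 genes with several transcripts the numbers were 328 (5.32%) and 176. Cbx7, a Polycomb chromodomain gene, had a first exon on chromosome 15 at 79801299 to 79801548 that was listed at 0 in both undifferentiated lanes and at 61.0 RPKM, 85.8% of the gene, in the differentiated library, and the transcript from it held 83.1%. A first exon of Wdr92, a WD-repeat gene (chromosome 11, 17082110 to 17082148), held 6.85% and 100%, and 1 of Fbxo11, an F-box gene (chromosome 17, 88464349 to 88464630), held 0% and 75.9%. For Strada, a kinase adaptor gene, the promoter share was 15.1% and 85.6%, and at least 46.4 points apart in each pairing of lanes. For Col14a1, a collagen gene, it was 2.55% and 78.4%, but the undifferentiated lanes gave 1.26% and 66.5%. Among transcripts, 1 form of Slc22a17 held 97.1% and 12.4% of its gene, 1 of Commd7 92.7% and 16.1%, and 1 of the chemokine gene Ccl27b 84.9% and 3.13%, where the undifferentiated lanes gave 88.2% and 39.2%.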

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

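Single lanes, genes with lanes within 2-fold, equal RPKM sums, informative symbols and the pairings of lanes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. The counts of 3446 higher and 1524 lower genes became 983 and 336 at a 4-fold threshold and 5698 and 3688 at 1.5-fold, by construction. With informative symbols alone the lower genes numbered 910 of 12190. In all other settings both counts lay within 1.5 times the values reported. For the lists, some settings could not change a call. Sums over transcripts or promoters equalled the gene values for all or nearly all genes, and median centring moves members and random lists alike. Leaving out genes held by several lists touched the primed epiblast and neural progenitor lists alone. Of 12 main lists 9 kept their side of the percentile limits in all 16 settings, these included. The neural progenitor list, not apart as reported, stood apart on the higher side in 10: with medians of 1.93 and 1.15 at pseudocounts of 0.1 and 0.5, 1.96 at a floor of 5 RPKM, 1.10 and 0.82 under trimmed-mean and upper-quartile scaling, 0.77 against unmatched lists, 0.90 without genes held by several lists, 0.87 and 0.94 in lane 1 and lane 2, and 1.22 for genes with lanes within 2-fold. The mesoderm list no longer stood apart with no floor (0.25), where silent genes enter. The neuron list stood apart on the lower side in lane 2 (-0.65) and with lanes within 2-fold (-0.61). Apart from those with a stated construction, the cause was not tested. Of 15 other lists 5 crossed a limit in some setting (neural crest, muscle, trophectoderm, p53 and cell death, reference genes). Of the values of 76 named genes in 10 settings, 415 moved by more than the lane error and 345 did not, and none changed sign. Most of these genes were named for large ratios, and the scalings shifted the median log2 ratio by at most 0.206. A change of sign under scaling was thus unlikely from the start, and its absence says little about stability. Many of the 345 come from the sums over transcripts and promoters, which repeat the gene values by construction, so that number overstates stability. Promoter and transcript counts moved with each limit, from 207 and 328 to 534 and 883 at a sum of 1 RPKM, 65 and 86 at 20 RPKM, 31 and 63 at 50 percentage points, and 112 and 176 in all 4 pairings of lanes. Depth limits the weakest genes: 1 read of a lane is worth 0.0265 to 0.0312 RPKM in a 1 kb model.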

Other observations

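The tests of the Gapdh locus, of overlapping gene models, of transcripts that differ between lanes and of feeder fibroblasts, and the lists for parietal endoderm, visceral endoderm and ribosomal proteins, were chosen after the results were seen.

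The endoderm genes of the differentiated library were unequal in level. Genes typical of parietal endoderm, which lays down the thick Reichert's membrane, were higher in 8 of 8 cases, with a median log2 ratio of 5.43 and a median level of 900 RPKM, from Thbd, thrombomodulin, at 7.36 to Sparc, a matrix glycoprotein gene, at 2360 RPKM. The laminin genes Lama1, Lamb1 and Lamc1 stood at 979, 843 and 775 RPKM. Genes typical of visceral endoderm, the absorptive layer, were higher in 7 of 8 cases, with a median log2 ratio of 1.93 and a median level of 5.50 RPKM. Cubn, at 129 RPKM, was far above the rest, followed by Ttr, transthyretin, at 21.7 and Afp, alpha-fetoprotein, at 7.54 RPKM, and without Cubn the medians were 1.61 and 5.23 RPKM. Levels of different genes are set by the genes as well as by cell type, so this is a contrast of levels alone.

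Ribosomal protein genes had log2 ratios below 0 in 84 of 85 cases, of which 4 were at least 2-fold lower, with a median of -0.71 at percentile 0.06 of matched random lists. The median ranged from -0.88 after trimmed-mean scaling to -0.48 with equal RPKM sums. Their share of the RPKM sum was 11.3% in the undifferentiated and 8.66% in the differentiated library, and many have processed copies that share reads.

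Serpinh1 and the basement membrane genes stood among the highest ratios, which led to the hypothesis that the machinery for folding and exporting collagen may be higher as a set. A list of 18 such genes without Serpinh1, written before its values were looked at, included prolyl and lysyl hydroxylases, Fkbp10, Sec23a, Sec24d and Creb3l2. Of the 18 genes 15 were at least 2-fold higher and none was 2-fold lower. Sec23a, Sec13 and Pcolce, named after their values were seen, lay between (log2 ratios 0.76, 0.49 and 0.02). Among the Sec genes of the list Sec24d alone was higher (1.81). The list median of 1.91 lay at percentile 100 of matched random lists. The hypothesis is consistent with this result in 1 library per condition, and which cells of the mixed population carry it was not analysed here.

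Gapdh, often used as a reference, was listed 11.6-fold lower in the differentiated library. The sum of Gapdh and the overlapping Gm10481 had a log2 ratio of -1.30 in the libraries and in both lanes, against -3.53 for Gapdh alone, so reads assigned to Gm10481 rather than Gapdh in the differentiated library are a candidate explanation for much of the difference. RPKM of models of unequal length do not add up as reads do, and how the authors assigned shared reads is not given in the sources used here. If the reads of Gm10481 come from Gapdh mRNA, that sum argues against a fall of Gapdh mRNA by the whole size listed. Their origin was not tested, so the sum alone cannot decide this. The 3 unnamed models with at least 90% of their 36-base words in Gapdh had a median log2 ratio of RPKM of -0.43. Over all 35 Gapdh-like models at the floor the median was -0.57 and the lowest -2.17, and 6 were over 2-fold lower. Such copies share reads with Gapdh, so their values depend on the unknown assignment and cannot decide the question. The size of any fall of Gapdh mRNA stays open.

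A few values differed over 4-fold between lanes of the same library, which no biological difference can give: 34 genes of the undifferentiated and 39 of the differentiated library at 10 RPKM or more, 73 values in all. Among transcripts 330 values did so, of which 62 would alone have moved their gene's sum over 2-fold. Reads moved between forms of a gene are not the main source of those 62, since 12.9% had a gene sum within 2-fold and 12.9% did with the lanes of the other forms swapped. Of 245 others with further forms, 149 (60.8%) were offset by over 50% in those forms and 49 were matched as far in the same direction, so moved reads may account for part of these. For genes, reads moved between overlapping models are not the main source: summing overlapping models brought 24.7% of the 73 values within 2-fold, and assignment among distant copies stays open, as not tested.

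Fibroblast collagens were higher in the differentiated library, where feeder cells had been removed before plating. A larger share of leftover feeder fibroblasts would raise all their abundant transcripts, but 7 of the 18 markers at the floor had log2 ratios under 0.5, and Postn, Lox, Col6a1 and Thy1 stood at 2.69 and 1.63, 2.502 and 2.46, 4.63 and 3.88, and 3.43 and 2.13 RPKM in the undifferentiated and differentiated library. That argues against feeder cells as the whole source. Parietal endoderm or mesenchyme among the differentiated cells stays open, as the design cannot separate cell types of a mixed population.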
